A study of Mus musculus with 6 samples.

How the data were processed

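The samples were Comma-Dβ cells, an established mouse mammary epithelial line, at passage 29. Per the labels' protocols, cells received 20 nM of a siRNA pool and were harvested after 48 hr. The siID4 arm received a siGENOME pool against mouse Id4 and the NT arm an ON-TARGETplus non-targeting pool, so the product line differed between the arms in every library. The labels describe 3 biological replicates per arm. Libraries were made from 1 µg of RNA with a poly(A)-selecting, strand-marking kit. The siRNA sequences are not given in the sources used here.

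The authors deposited a single table of expected counts per gene, with one column per library and a gene length column. The submitters' processing notes name cutadapt, STAR, RSEM and the genome build mm10, with no versions. The annotation release, the strand setting of the counting and the rule behind the table's description as filtered are not given in the sources used here. Expected counts divide reads that fit several genes between them by estimate, so values of near-identical genes depend on that estimate. Between 10.0% and 10.6% of the values in a library were not whole numbers (any remainder counted, tolerance 0), or 13.8% to 14.3% of the values above 0, and all were rounded to whole numbers before testing. The table held 25655 genes, of which 2882 were at 0 in all 6 libraries. Each column was assigned to the sample whose siRNA and replicate number its name gives. The further number in each column name is not explained by the labels and was not used.

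Gene coordinates, biotypes and 3' UTRs were taken from GENCODE release M21 on GRCm38, the assembly also called mm10, by matching gene identifiers. Of the 25655 genes, 25325 matched and 330 did not.

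Total counts per library were between 19.2 M and 23.1 M. The mitochondrial share was between 3.52% and 4.08% of counts, and the 10 most abundant genes took between 6.23% and 6.96%. At these depths the spread between replicates was described by a biological coefficient of variation of 7.83% over the genes tested. No library pair of the same arm agreed within sampling noise (chi-square per gene from 5.13 to 13.9), so each library was counted as its own replicate.

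The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with robust dispersion estimates, TMM scaling and group as the only term. filterByExpr kept 13941 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values printed for single genes are from that test unless another is named. Levels are CPM scaled by TMM, as mean ± SD over 3 libraries. Standard errors (SE) of log2 fold changes were derived from the F statistic. For single genes an exact two-sided permutation test of 3 against 3 libraries cannot give a p below 0.1.

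Before the data were examined, 32 gene lists were fixed, among them markers of fibroblasts, endothelial cells, leukocytes and adipocytes. The 29 lists with at least 5 genes tested were compared with all other genes by limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Counts per list are given over all genes tested and adjusted over the list alone. Camera was repeated with the correlation estimated from each list, and fry was run as a test of the list's own genes.

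The genes to be named were also set by rule. They are Id4 and the helix-loop-helix (HLH) genes Id1, Id2, Id3, Tcf3, Tcf4 and Tcf12, then the 8 genes that rose most and the 8 that fell most among called genes with a mean of at least 5 CPM and no overlap between the arms. To these come up to 4 members with the smallest adjusted p from each list that passed camera or held at least 3 called members. Members of the contractile, basal, luminal and milk lists with at least 1 CPM could be named whatever their test gave. Predicted and unnamed gene models were passed over in the ranking. Genes outside this rule are said to be so where they appear.

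The arms share replicate numbers. Same-numbered libraries deviated together from their group means in all 3 pairs (correlation across genes 0.42, 0.14 and 0.38). With other numbers it was at most −0.02, over genes that are not independent replicates. Deviations cancel within each arm by construction, so positive correlations within numbers force negative ones with other numbers on balance. The main test leaves this pairing out of its model. The fit with a block and the differences within numbers use it. The labels do not say what the pairs share. The fit with the number as a block was planned as an alternative, and its counts are given beside the totals, lists and families it moved, and beside single genes discussed in the text whose call it changed.

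The alternatives set before the data were examined were DESeq2 size factors, upper quartile scaling and library totals in place of TMM, no filter on low counts, a minimum mean of 5 CPM, DESeq2 (1.42.0), limma-voom, the replicate block, each library left out in turn, an adjusted p under 0.01, a minimum change of 1.5-fold, a test against a 1.2-fold change (glmTreat), and smooth corrections for GC content and gene length. Fits without the genes that hold one 7-base sequence in the 3' UTR were added after the data were seen.

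For the association with 3' UTR sequence, log2 fold changes of 12433 genes with an annotated 3' UTR of at least 50 bases, Id4 left out, were regressed on the presence of each of 15796 7-mers found in at least 100 of them, with UTR length and GC content in the model. The longest annotated 3' UTR of each gene was used.

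The scripts were tested on simulated data. In the simulated counts, changed genes and raised lists were drawn only from genes with a mean of at least 5 CPM. No effect shared within replicate numbers was simulated. In 10 simulated sets of siID4 against NT with per-gene dispersions and a median of 13942.5 genes tested, 91.2% of genes changed 1.5-fold and 98.7% of those changed 2-fold were recovered, and 8.53% of calls were false, above the nominal 5%. In 10 further sets with dispersions drawn from the trend and a median of 13935.5 genes tested, these were 93.2%, 99.9% and 4.55%. Camera recovered 5 of 5 raised lists among 20, with 13950 genes tested. The simulated genes were drawn independently, while correlations estimated in the real lists reached 0.85 (interferon) and 0.72 (S phase). This recovery therefore says nothing about lists whose genes move together. With shuffled fold changes over the 12433 genes, the lowest z of any 7-mer in 10 shuffles was −4.07. A shift given to one 7-mer in each of 10 such sets put it first in 8, and in 4 of 4 sets where the 7-mer was common. Computation outside R used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.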

Results

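The transcriptome of Comma-Dβ cells was measured by RNA sequencing after transfection of a siRNA pool against Id4 (siID4) or a non-targeting pool (NT), with 3 biological replicates per arm. Comma-Dβ is a mouse mammary epithelial line. The series asks how loss of ID4 changes gene expression in these cells. The NT libraries held 20.2, 19.2 and 23.1 M counts and the siID4 libraries 23.1, 21.7 and 22.7 M. Log2 expression correlated across genes at 0.991 to 0.994 within an arm and 0.985 to 0.990 between arms, with genes not being independent replicates. The first principal component held 43.1% of the variance and placed the 3 NT libraries on one side and the 3 siID4 libraries on the other.

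Id4 mRNA was lowered and not removed. Id4 (ENSMUSG00000021379) encodes an inhibitor of DNA binding, a helix-loop-helix (HLH) protein without a DNA-binding region that pairs with other HLH proteins. Its level was 135, 114 and 118 CPM in the NT libraries and 59.4, 62.2 and 48.2 CPM in the siID4 libraries. The mean went from 122 ± 11.5 to 56.6 ± 7.41 CPM (SD, n = 3 per arm, exact permutation p = 0.1, the smallest possible), or 0.463 of the NT level. The log2 fold change was −1.11 (SE 0.10, edgeR adjusted p = 8.65e-04). The gene lies on chromosome 13 from 48261228 to 48266026 on the plus strand of GRCm38 and is annotated as protein-coding.

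**Figure D1:**
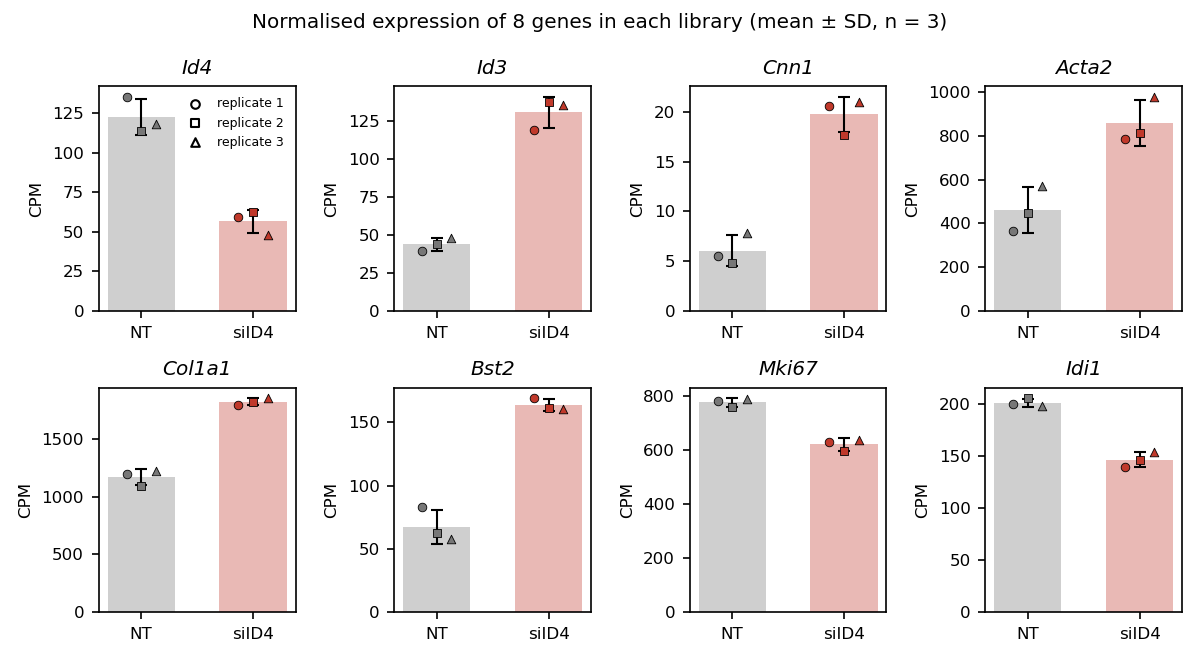
Normalised expression of 8 genes in each library, in CPM with TMM scaling. Bars are means and error bars SDs over 3 libraries, and the marker shape gives the replicate number. In each of the 8 panels the NT and siID4 libraries do not overlap, with Id4, Mki67 and Idi1 lower and Id3, Cnn1, Acta2, Col1a1 and Bst2 higher in siID4.

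Beside the fall of Id4, the siID4 cells held more mRNA of contractile, matrix and interferon-inducible genes and less of genes of cholesterol synthesis, glycolysis and mitosis, by a camera test with a preset correlation. With a correlation estimated from each list, 0 of 29 lists passed. Of 13941 genes tested, 1331 changed, 644 upward and 687 downward. The increases were larger. Among called genes, 270 rose and 100 fell by at least 1.5-fold, and 117 rose and 24 fell by at least 2-fold. The median log2 fold change was 0.52 for genes that rose and −0.33 for genes that fell. A mean of at least 5 CPM was reached by 527 of the 644 that rose and 657 of the 687 that fell. Whether the larger share of genes of low expression accounts for the larger increases was not tested. All 1331 had arms that did not overlap, as did 30.9% of all genes tested, where chance gives 10%. With library totals in place of TMM, 829 rose and 564 fell. With the replicate number as a block, 5038 changed, 2493 upward and 2545 downward, and 1325 of the 1331 were among them. The count without one library was 631 without NT replicate 2, 884 without siID4 replicate 1 and 445 without siID4 replicate 2, and the count of genes that rose was 423 without NT replicate 3.

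The 8 genes that rose most were Tgtp1, Oas2, Cnn1, Tnn, Id3, Tagln, Usp18 and Wisp2. Tgtp1, an interferon-inducible GTPase, went from 3.31 ± 0.898 to 12.7 ± 0.879 CPM, a value made uncertain by its near-identical neighbour Tgtp2. Tnn, a tenascin of the extracellular matrix, went from 3.49 ± 0.511 to 11.1 ± 3.27 CPM, and Wisp2, a secreted protein of the CCN family, from 28.7 ± 5.94 to 74.2 ± 5.96 CPM. The 8 that fell most were S1pr2, Id4, Slc16a1, Ywhah, Gsta1, Evi2a, Tgfbr3 and Gchfr. S1pr2, a receptor for sphingosine phosphate, had a log2 fold change of −1.16 (SE 0.10, adjusted p = 3.91e-04). Slc16a1, a lactate transporter, went from 126 ± 3.48 to 59.3 ± 3.09 CPM (log2 fold change −1.08, SE 0.05, adjusted p = 4.76e-05). Ywhah, an adaptor protein that binds phosphorylated partners, went from 299 ± 18.8 to 143 ± 1.24 CPM (log2 fold change −1.06, SE 0.05, adjusted p = 4.76e-05). These 3 fell about as far as the siRNA target itself. With no filter on low counts, Usp18 (adjusted p = 0.0590), Gsta1 (0.0757) and Tgfbr3 (0.0674) did not pass. Without siID4 replicate 2, Evi2a (adjusted p = 0.0932), Tgfbr3 (0.0528) and Gsta1 did not pass, and Gsta1 passed in 2 of the 6 fits that left out one library.

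Id3, a relative of Id4 and one of the 8 genes that rose most, went from 43.8 ± 4.48 to 131 ± 10.3 CPM (log2 fold change 1.58, SE 0.08, adjusted p = 6.07e-05). The other HLH genes fixed beforehand did not pass in the main test. Id1 was 36.4 ± 10.4 CPM in NT and 54.5 ± 11.4 CPM in siID4 (log2 fold change 0.58, SE 0.22, adjusted p = 0.161), and Id2 had a log2 fold change of 0.26 (SE 0.11, adjusted p = 0.161). The E protein genes, whose products pair with ID proteins, had log2 fold changes of −0.04 (Tcf3), 0.32 (Tcf4) and 0.09 (Tcf12). With the replicate block Id2 (adjusted p = 2.26e-04), Tcf4 (3.45e-10) and Tcf12 (0.0168) passed, and Tcf4 also did with DESeq2 (0.0258). In edgeR fits without one library, Id1 passed without NT replicate 3 (adjusted p = 0.0317). Tcf4 passed without NT replicate 1 (0.0313) and without siID4 replicate 3 (0.0376). Of 10 genes on the list of HLH partners, Id3 and Myc rose (2 adjusted over the list alone, 6 up and 1 down with the block). The list's camera adjusted p was 0.0225, 0.0607 without NT replicate 2 and 0.0655 without siID4 replicate 2 (adjusted p = 0.238 with an estimated correlation). Of 14 measured genes that respond to bone morphogenetic proteins (BMPs), 4 rose, and 4 adjusted over the list alone. They were Id3, Bmp4, Atoh8 and Smad6, and with the block 5 rose and 1 fell. Bmp4, which encodes one such ligand, went from 3.06 ± 0.859 to 6.36 ± 0.491 CPM. Without siID4 replicate 2, Bmp4 (adjusted p = 0.0542), Atoh8 (0.121) and Smad6 (0.145) did not pass, nor did Smad6 with DESeq2 (0.0550) or Myc without NT replicate 2 (0.0740). Atoh8 and Smad6 each passed in 1 of the 6 fits without one library. The camera adjusted p was 0.0241 (0.238 as adjusted p with an estimated correlation), and it was 0.0738 with the block, 0.0880 at a mean of at least 5 CPM and 0.0648 without NT replicate 1.

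Genes of the smooth muscle contractile apparatus, which myoepithelial cells of the mammary gland use to eject milk, rose as a group. Of 14 measured, 7 rose and the other 7 did not pass (13 rose adjusted over the list alone, and 13 with the block). The list median log2 fold change was 0.60, and camera gave an adjusted p of 3.09e-07 (adjusted p = 0.238 with an estimated correlation). Cnn1, which encodes the actin-binding protein calponin, went from 6.05 ± 1.58 to 19.7 ± 1.77 CPM (log2 fold change 1.69, SE 0.16, adjusted p = 7.85e-04). Tagln, which encodes transgelin, went from 26.4 ± 6.89 to 76.8 ± 12.8 CPM (1.54, SE 0.19, adjusted p = 0.00400). Acta2, smooth muscle actin, went from 461 ± 104 to 858 ± 105 CPM (0.90, SE 0.17, adjusted p = 0.0195). Tpm1, Myl9, Lmod1 and the oxytocin receptor gene Oxtr rose by log2 fold changes of 0.41, 1.00, 1.61 and 1.04. Mylk (0.72, adjusted p = 0.0729), Actg2 (0.46, adjusted p = 0.118) and Smtn (0.01, adjusted p = 0.940) did not pass, and Mylk and Actg2 did with the block (adjusted p = 1.77e-08 and 3.60e-05), Mylk also with DESeq2 (0.00793). With no filter on low counts Acta2 (adjusted p = 0.125), Myl9 (0.0683) and Oxtr (0.0892) did not pass. Acta2 passed in 2 of the 6 fits without one library, with a highest adjusted p of 0.0603, Lmod1 in 4 (0.0614) and Oxtr in 1 (0.105). Cnn1 and Tagln passed in all 6. Fibroblast markers (median 0.48) and the 4 endothelial and pericyte markers tested (median 0.62, 4 up adjusted over the list alone) were higher as well.

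Markers of basal and luminal identity did not move as groups. Among 17 basal markers, Snai2 and Trp63, transcription factors of basal cells, rose (log2 fold changes 0.31 and 0.27), and Dsc3 and Itgb4, which encode adhesion proteins, fell (−0.44 and −0.24). The same 2 up and 2 down were counted adjusted over the list alone, and 5 up and 5 down with the block. Krt5 and Krt14 had log2 fold changes of −0.18 and −0.11 (adjusted p = 0.165 and 0.542). Among 21 luminal markers Gata3 (0.36) and Kit (0.91) rose and Areg (−0.58) and Epcam (−0.25) fell (3 up and 2 down adjusted over the list alone, 6 and 8 with the block). Krt8, Krt18 and Elf5 had log2 fold changes of −0.23, −0.15 and −0.30, with adjusted p from 0.110 to 0.682. With the block Krt5, Krt8, Krt18 and Elf5 passed (adjusted p = 4.65e-05, 1.77e-06, 6.05e-04 and 0.00333). Of 5 milk protein genes tested, Btn1a1 rose (0.64) and Ltf fell (−0.79), as they did adjusted over the list alone (2 up and 2 down with the block). Ltf did not pass with no filter on low counts (adjusted p = 0.132). Each of these basal, luminal and milk genes lost its call in at least 2 of the 6 fits without one library. Camera adjusted p was 0.790 for the basal, 0.789 for the luminal and 0.952 for the milk list, whose median (0.02) and mean (−0.03) differ in sign.

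Interstitial matrix genes rose. Of 21 measured, 10 rose and the others did not pass (13 up and 1 down adjusted over the list alone, 18 up and 2 down with the block). The median log2 fold change was 0.53, with a camera adjusted p of 3.07e-06 (adjusted p = 0.377 with an estimated correlation). Col1a1, the main chain of fibrillar collagen I, went from 1171 ± 69.8 to 1817 ± 31.3 CPM (log2 fold change 0.63, SE 0.05, adjusted p = 3.91e-04). Postn, which encodes periostin, went from 225 ± 12.7 to 385 ± 36.0 CPM (0.78, SE 0.07, adjusted p = 6.31e-04). Col5a1 rose by 0.56 and Sparc by 0.30 on the log2 scale. Markers of fibroblasts moved with these genes. Of 11 tested, 4 of which also stand on the matrix list, 4 rose and 1 fell (7 and 1 adjusted over the list alone, 8 and 2 with the block), with a median of 0.48 and a camera adjusted p of 0.00139 (adjusted p = 0.377 with an estimated correlation). Cxcl12 rose by 0.68, Col1a2 by 0.40 and Pdgfrb by 0.43. Pdgfra, named after its values were seen, had a log2 fold change of −0.62 (adjusted p = 0.0257). Without siID4 replicate 2, Pdgfrb (adjusted p = 0.0890) and the inhibitor gene Timp1 (0.140) did not pass. Among 18 matrix proteases and inhibitors, 2 rose and 1 fell, with Timp3 (0.46) and Timp1 (−0.22) among them. Adjusted over the list alone 3 rose and 1 fell, and with the block 12 rose and 4 fell. Its camera adjusted p was 0.0303, 0.0951 without NT replicate 2 and 0.0912 without siID4 replicate 1 (adjusted p = 0.238 with an estimated correlation). Over genes without the sequence GACTGCT in the 3' UTR the camera adjusted p was 0.0550.

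Basement membrane genes and collagen-modifying enzymes did not pass camera as lists. Lama4 (0.44), Hspg2 (0.19) and Col4a5 (0.42) rose among 15 basement membrane genes (4 up and 2 down adjusted over the list alone, 6 and 3 with the block, camera adjusted p = 0.272). Hspg2 and Col4a5 each passed in 1 of the 6 fits without one library and failed after GC correction (adjusted p = 0.0562 and 0.0556). Hspg2 also failed after length correction (0.103), and Col4a5 with no filter on low counts (0.110) and without genes that hold GACTGCT in the 3' UTR (0.0557). Plod1, Adamts2 and P4ha3, enzymes that process collagen, rose by 0.39, 0.50 and 0.94, and the collagen glycosyltransferase gene Colgalt1 fell (−0.48, adjusted p = 0.00129), with P4ha3 at an adjusted p of 0.0533 without siID4 replicate 2. Over those 16 enzymes 4 rose and 2 fell adjusted over the list alone, 7 and 2 did with the block, and the camera adjusted p was 0.173 (0.0158 as adjusted p by fry).

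Interferon-inducible genes rose, from a base that varied among the NT libraries. Of 22 measured, 7 rose and 1 fell (17 and 1 adjusted over the list alone, 13 and 2 with the block), and DESeq2 and limma-voom each called 15. The median log2 fold change was 0.78 and the camera adjusted p 3.09e-07 (adjusted p = 0.464 with an estimated correlation). The fry adjusted p was 0.0807. Oas2, an oligoadenylate synthetase, went from 3.37 ± 0.645 to 12.6 ± 1.88 CPM (log2 fold change 1.91, SE 0.17, adjusted p = 5.85e-04). Bst2, which encodes the antiviral membrane protein tetherin, went from 67.7 ± 13.3 to 164 ± 4.70 CPM (1.27, SE 0.12, adjusted p = 0.00123). Usp18, a protease that removes ISG15 from proteins, rose by 1.47. Cxcl10, named after its values were seen, fell (−0.51). The mean deviation of the list's members from their mean over the 6 libraries was 0.01, −0.34 and −0.86 log2 units in NT replicates 1 to 3, and 0.55, 0.41 and 0.23 in the same-numbered siID4 libraries. Of 16 genes of NF-κB and inflammation, Icam1 rose (1.61) and Ccl2 (−0.73) and Csf1 (−0.26) fell (2 up and 3 down adjusted over the list alone, 3 and 8 with the block, 6 called by DESeq2, camera adjusted p = 0.426). Csf1 did not pass with library totals (adjusted p = 0.0580) or at a mean of at least 5 CPM (0.0501), and passed in 1 of the 6 fits without one library.

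**Figure D2:**
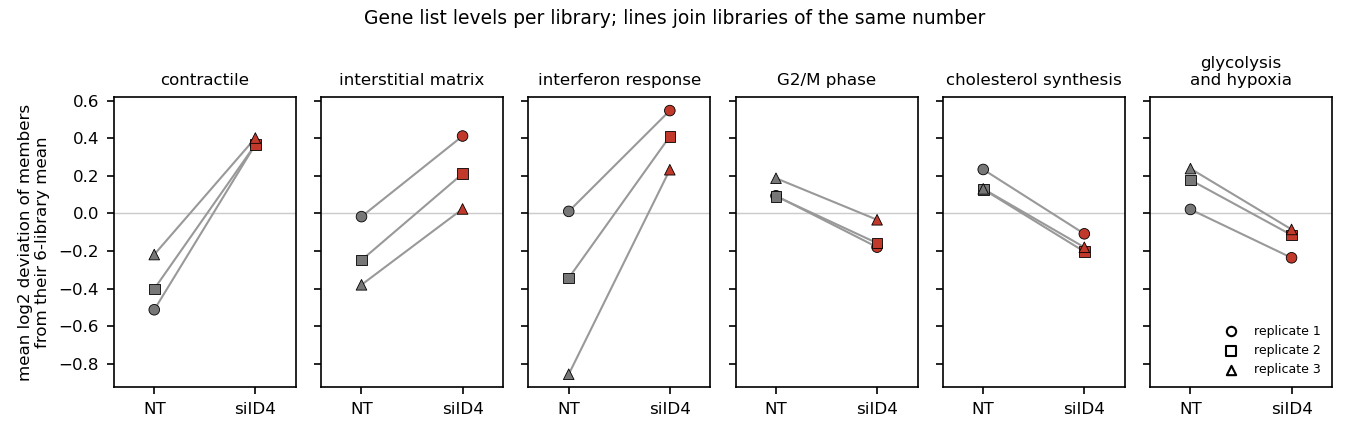
Level of 6 gene lists in each library, as the mean log2 deviation of the members from their own mean over 6 libraries. Lines join libraries of the same replicate number. In every pair the contractile, interstitial matrix and interferon lists are higher and the G2/M, cholesterol synthesis and glycolysis lists lower in siID4.

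Genes of the cholesterol synthesis pathway fell together. Of 22 measured, 14 fell and the others did not pass (21 fell adjusted over the list alone, and 21 with the block). The median log2 fold change was −0.34 and the camera adjusted p 3.63e-12 (adjusted p = 0.238 with an estimated correlation). Idi1, an isomerase of the pathway, went from 201 ± 3.90 to 146 ± 6.97 CPM (log2 fold change −0.46, SE 0.05, adjusted p = 0.00123). Fdps and Pmvk, further enzymes of the pathway, fell by 0.34 and 0.42 on the log2 scale, and Stard4, a sterol carrier, by 0.64. Glycolytic and hypoxia-responsive genes also fell, 12 of 22 measured (14 adjusted over the list alone, 17 with the block), with a median of −0.30 and a camera adjusted p of 3.19e-08 (adjusted p = 0.238 with an estimated correlation). Ldha, lactate dehydrogenase, went from 1424 ± 43.7 to 1145 ± 32.0 CPM (−0.31, SE 0.04, adjusted p = 0.00389). Tpi1 and Pgk1 fell by 0.30 and 0.33 and Vegfa, an angiogenic growth factor gene, by 0.45 (adjusted p = 0.0508 without siID4 replicate 2).

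Genes of mitosis fell by small amounts, with log2 fold changes of the members from −0.41 to −0.06. Of 22 G2/M genes, 13 fell (21 adjusted over the list alone, and 21 with the block), with a median of −0.26 and a camera adjusted p of 3.24e-10 (adjusted p = 0.346 with an estimated correlation). Mki67, a marker of proliferating cells, went from 777 ± 15.3 to 621 ± 22.5 CPM (log2 fold change −0.32, SE 0.04, adjusted p = 0.00326). Hmmr, Kif11 and Top2a fell by 0.41, 0.30 and 0.30 on the log2 scale. Of 22 S phase genes 4 fell, namely Mcm5, Tyms, Mcm6 and Uhrf1 (9 adjusted over the list alone, 15 with the block). Their median was −0.14 and the camera adjusted p 3.47e-04 (adjusted p = 0.528 with an estimated correlation, 0.194 by fry). Mcm6 passed in 0 of the 6 edgeR fits without one library (adjusted p up to 0.184) and failed with library totals (0.0571), as did Uhrf1 (0.0578). Without siID4 replicate 2, Top2a (adjusted p = 0.0546), Mcm5 (0.0690), Tyms (0.0765) and Uhrf1 (0.185) did not pass. The cyclin gene Ccnd1, on the list of Wnt targets, fell by 0.33.

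Genes that respond to TGF-β rose by smaller amounts. Of 17 measured, 6 rose (6 adjusted over the list alone, 11 up and 1 down with the block), with a median of 0.25 and a camera adjusted p of 3.42e-04 (adjusted p = 0.238 with an estimated correlation). Ltbp2, Tgfbr2 and Tgfb3 rose by 0.53, 0.30 and 0.36. Of 22 targets of the transcriptional coactivators YAP and TAZ, 7 rose and 2 fell (9 and 2 adjusted over the list alone, 13 and 3 with the block). Their camera adjusted p was 0.0160 (adjusted p = 0.346 with an estimated correlation), and 0.217 over genes without the sequence GACTGCT in the 3' UTR. Rbms3 (0.54), Amotl2 (0.47) and Lats2 (0.39) rose, and Nt5e (−0.32) fell. Of 21 actin cytoskeleton and focal adhesion genes, 5 rose (7 adjusted over the list alone, 13 with the block), with a camera adjusted p of 0.00232 (adjusted p = 0.528 with an estimated correlation, 0.0858 by fry). Lima1 (0.29), Csrp1 (0.35), Zyx (0.26) and Vasp (0.21) were among them. The fifth, Flnc (0.20), and the second YAP/TAZ target that fell, Myof (−0.20), lie outside the naming rule. Tgfbr2 (adjusted p = 0.0569) and Tgfb3 (0.114) did not pass without siID4 replicate 2, nor Zyx (0.0817) and Vasp (0.0818) without NT replicate 2.

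**Figure D3:**
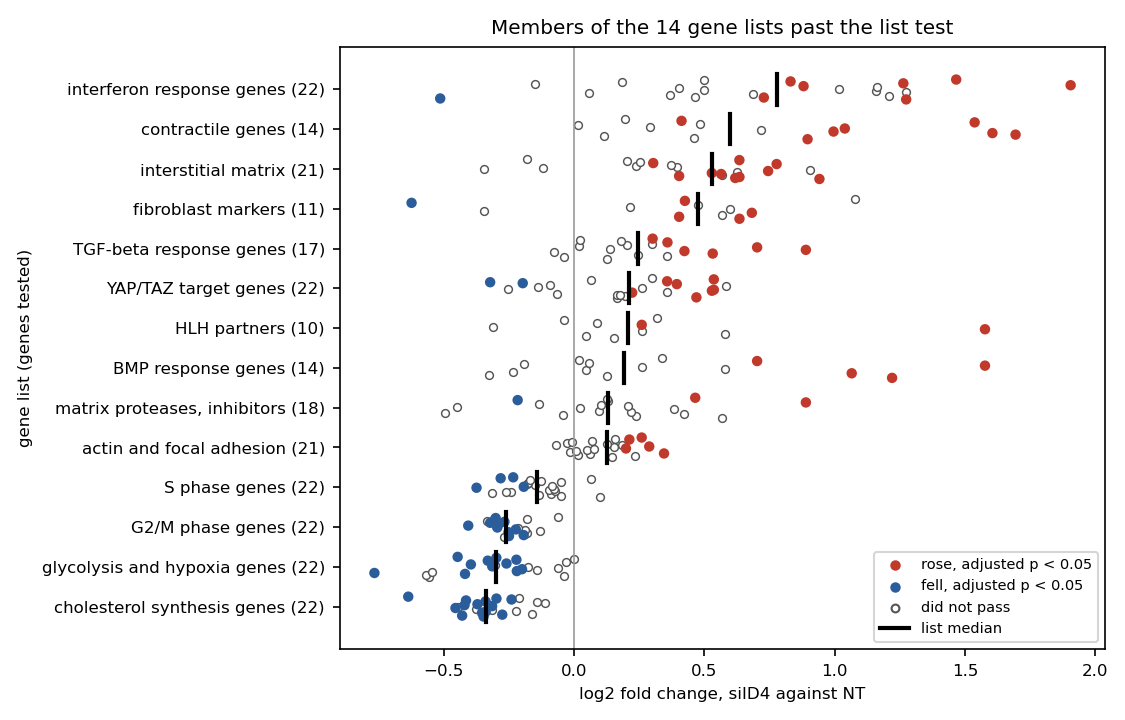
Log2 fold change of each tested member of the 14 gene lists past the camera test, with the number of genes tested in brackets. Filled points passed an adjusted p of 0.05, open points did not, and bars are list medians, which run from −0.34 for cholesterol synthesis to 0.78 for the interferon response.

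In all, 14 of 29 lists passed camera with the preset correlation, 10 upward and 4 downward. With a correlation estimated from each list 0 passed, and 4 had an unadjusted camera p under 0.05. The other lists did not pass camera in the main fit. Among 15 regulators and markers of epithelial to mesenchymal transition, Snai2, Zeb2 (0.33) and Itga5 (0.26) rose and Vim (−0.39) fell (6 up and 2 down adjusted over the list alone, 9 and 5 with the block, camera adjusted p = 0.267, fry adjusted p = 0.00811). Without siID4 replicate 2, Zeb2 (adjusted p = 0.129) and Vim (0.114) did not pass, and Itga5 passed in 1 of the 6 fits without one library. Among 22 epithelial junction genes, Cdh1 (0.24) rose and Epcam fell, the same counts as adjusted over the list alone (2 and 6 with the block, camera adjusted p = 0.193). Notch pathway genes gave 2 up of 13 (Dll1 and Notch3, 4 adjusted over the list alone, 6 up and 1 down with the block, camera adjusted p = 0.0603). Of 11 Wnt targets, Lef1 (0.64) rose and Ccnd1 and Notum (−0.53) fell (2 up and 2 down adjusted over the list alone, 4 and 2 with the block, camera adjusted p = 0.426), and Lef1 did not pass with DESeq2 (adjusted p = 0.0938) or in any fit without one library, nor Notum without NT replicate 2 (0.0877). Of 18 p53 targets Sesn2 rose (1 adjusted over the list alone, 6 up and 2 down with the block, camera adjusted p = 0.575). Of 18 genes of the unfolded protein response Pdia6 and Asns fell (2 adjusted over the list alone, 3 up and 8 down with the block, camera adjusted p = 0.485). Cdh1, Dll1, Notch3, Sesn2, Pdia6 and Asns were named after their values were seen.

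In edgeR's test 0 of 17 immediate early genes, 0 of 14 heat shock genes and 0 of 13 mitochondrially encoded genes changed, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 these lists held 5, 1 and 3 genes, DESeq2 called 2, 0 and 2, limma-voom called 0, 0 and 0, and the block gave 2 up and 8 down, 2 and 5, and 0 and 3. Their camera adjusted p was 0.173, 0.671 and 0.635, and the mitochondrial list's median (−0.07) and mean (0.03) differ in sign. Markers of endothelial cells, adipocytes and leukocytes were too few among the genes tested for a list test. Of 4 endothelial and pericyte markers tested Flt1 and Notch3 rose (4 adjusted over the list alone, and 4 with the block). Of 3 adipocyte markers Lpl rose (1 adjusted over the list alone). Of 3 leukocyte markers 0 changed by edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p under 0.05. Flt1 and Lpl lie outside the naming rule.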

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

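The fit without genes that hold GACTGCT in the 3' UTR was chosen after the result was seen. Id4 itself holds that sequence and was not in that fit. In all other fits the fall of Id4 kept its direction and passed, with log2 fold changes from −1.18 to −1.01. Under the scaling, filter, test, GC and length alternatives the count of changed genes stayed between 1242 and 1489, against 1331, and it was 1032 without genes that hold GACTGCT. No gene called in the main test changed sign under any alternative.

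The replicate block raised the counts to 5038 (2493 up, 2545 down), and leaving libraries out gave totals from 445 to 1351, with 221 to 686 up and 224 to 665 down. Dropping a library lowers power by construction. Without its replicate 2 an arm keeps replicates 1 and 3, its most different pair. Chi-square per gene was 13.9 for that pair in NT and 10.8 in siID4, against at most 7.30 for other same-arm pairs. Whether this wider spread is why siID4 replicate 2 (445) and NT replicate 2 (631) weigh more than the others was not tested. Stricter thresholds gave, by construction, 451 genes at an adjusted p under 0.01 (206 up, 245 down), 370 with at least a 1.5-fold change (270 and 100) and 241 in glmTreat against 1.2-fold (148 and 93). Of 90 named genes that passed, 49 passed in all 6 fits without one library.

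Of the 14 lists past camera, 0 passed with an estimated correlation (4 of 29 at an unadjusted p under 0.05). Adjusted p was then 0.238 for the contractile, protease, TGF-β, BMP, HLH, cholesterol and glycolysis lists, 0.377 for the matrix and fibroblast lists, 0.346 for YAP/TAZ and G2/M, 0.464 for interferon, and 0.528 for actin and S phase. By fry 13 lists passed, among them collagen processing (0.0158) and epithelial to mesenchymal transition (0.00811), which had not passed camera, while actin (0.0858), S phase (0.194) and interferon (0.0807) did not. The BMP list lost its call with the block (0.0738), at a mean of at least 5 CPM (0.0880) and without NT replicate 1 (0.0648). Over the fits without one library the adjusted p ran from 0.01004 to 0.0648 for the BMP list, from 0.0114 to 0.0951 for the protease list (0.0912 without siID4 replicate 1) and from 0.0152 to 0.0655 for the HLH list (0.0607 without NT replicate 2). Without genes that hold GACTGCT, 12 of the 14 lists kept their call and 1 further list gained one, while the protease list had 0.0550 and YAP/TAZ 0.217. The cause of these losses was not tested. Beside the results printed with it, the block changed no list call and ended no call of a named gene, while 31 named genes that had not passed did so with it, some of them also under other alternatives.

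With 19.2 to 23.1 M counts per library, the simulated recovery of 1.5-fold changes was 91.2% for genes with a mean of at least 5 CPM. Recovery of genes below that level was not simulated. With each library left out, camera called 13 to 16 lists. Of the 14 lists of the main fit 12 to 14 were kept, so lists outside these 14 passed in some of these fits.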

Other observations

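Gene families not fixed beforehand were chosen after their values were seen, so they describe the interferon and matrix results further and do not test them. Of 18 interferon-inducible GTPase genes tested, whose products defend cells against intracellular pathogens, 12 rose and the others did not pass (15 rose with the replicate block), with a median log2 fold change of 1.14. Gbp2 rose by 1.16, Gbp7 by 1.11, Irgm1 by 0.98 and Iigp1 by 1.35, while several members are near-identical copies whose reads are hard to divide. Of 24 genes of class I antigen presentation, which displays peptides from inside the cell, 18 rose (22 with the block), with log2 fold changes over the family from 0.28 to 0.87 and the transporter gene Tap2 (0.57), the immunoproteasome gene Psmb8 (0.67) and B2m (0.46) among them. Of 32 collagen chain genes, several of them also on the matrix list, 12 rose (23 up and 2 down with the block), with a median of 0.54.

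Smaller shifts appeared in 3 further families chosen in the same way. Of 73 ribosomal protein genes 9 fell (40 down and 2 up with the block), with a median of −0.08 (−0.05 with library totals). Rpl26 stood apart at −0.80 (adjusted p = 6.07e-05) and Rps2, which has near-identical pseudogenes, at −0.63. Of 17 keratin genes Krt6a (−0.91) and Krt6b (−0.83) fell, keratins of activated epithelium (10 down and 1 up with the block), with a median of −0.27 (−0.24 with library totals). Of 16 targets of the oxidative stress factor NRF2, 5 fell (9 down and 2 up with the block), among them Gclm (−0.74) of glutathione synthesis and Nqo1 (−0.62).

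Among the tests below, the one of genes without GACTGCT, the one of abundant leukocyte transcripts and the SE of differences within numbers were chosen after the result was seen. In the first pattern, genes of unrelated functions fell about as far as Id4. The 7-mer whose presence in the 3' UTR went with the lowest log2 fold change was GACTGCT (z = −10.9, against −6.13 for the next and 5.47 for the highest of 15796), which lies in the Id4 mRNA on GRCm38 chromosome 13 at 48261705 to 48261711 in the coding part of exon 1 and at 48263296 to 48263302 and 48265282 to 48265288 in the 3' UTR of exon 3. Of genes with 0, 1, and 2 or more such sites 4.23%, 11.2% and 18.0% fell, and 202 of 657 fallen genes (30.7%) held one, against 12.7% of unchanged genes. Unlike z, these shares were not adjusted for UTR length or GC content, and longer UTRs have room for more sites. Stard4, Vegfa, Kif11, Top2a, Colgalt1 and Rpl26, which fell, also hold GACTGCT, as do Col5a1, Tgfb3, Rbms3 and Amotl2, which rose. Without genes that hold it, 9 of 15 G2/M, 10 of 16 cholesterol synthesis and 9 of 17 glycolysis genes fell. In the main test these were 13, 14 and 12 of 22. The 3 lists still passed camera with the preset correlation. Of the 10 lowest 7-mers 6 lie in Id4, a number reached by 3.48% of 1841 mRNAs of similar length and GC content. Among these, AGACTGC (z = −6.13), TGACTGC and ACTGCTA are GACTGCT shifted by 1 base. They overlap it in Id4 and are not separate hits. Of the 10 highest 7-mers 6 lie in Id4 as well (5.11% of those mRNAs hold as many). After removal of genes with GACTGCT the lowest was CAGGGTG (z = −5.44), also in Id4. Bias by GC content or gene length is argued against, since at least 93.0% of fallen genes passed after either correction, while seed matches of the siRNA pool may account for part of the fall, with a site in S1pr2, Ywhah, Evi2a and Tgfbr3 but none in Slc16a1, Gsta1 and Gchfr among the genes that fell most, a hypothesis left open because the siRNA sequences were not used here and a response to Id4 loss was not tested apart from it.

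In the second pattern interferon-inducible genes rose. The planned test of carried leukocytes compared the median of 3 leukocyte markers (0.58) with the interferon median (0.78). It met the criterion set for leukocytes, a difference (0.20) within 1 SE (0.35). That SE was taken over genes as if independent and does not measure the spread between libraries. The planned test also rested on 3 genes of low expression, and another test was chosen after that outcome was seen. That later test argues against leukocytes carried along, since of 5 abundant leukocyte transcripts (Ptprc, Cd74, Lyz2, Laptm5 and Fcer1g) the highest mean in siID4 was 0.489 CPM, while the interferon genes together gained 650 CPM, although of the other leukocyte markers Cd68 was at 2.16 CPM in NT and 2.23 CPM in siID4 and Csf1r at 0.761 and 1.17 CPM, with a gain of all 10 together of 0.974 CPM. An effect shared alike by both libraries of a number is argued against by the design, in which it cancels between the arms, and by list means higher in siID4 by 0.54, 0.75 and 1.09 log2 units within numbers 1 to 3 (mean 0.79, SE 0.16; camera adjusted p = 1.89e-06 with the block, and adjusted p = 0.464 with an estimated correlation and no block). The siRNA product line cannot be told apart from the target, because 0 libraries received a pool of the other arm's line, so a response to the siRNA itself, or to loss of Id4, may underlie the rise.

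In the third pattern, contractile and matrix genes rose. An effect shared within numbers is argued against in the same way, by contractile list means higher in siID4 by 0.88, 0.77 and 0.62 log2 units (mean 0.76, SE 0.08; camera adjusted p = 1.52e-07 with the block, and adjusted p = 0.238 with an estimated correlation and no block). Fibroblast-like cells could contribute. The 7 fibroblast markers on no other list had a median log2 fold change of 0.48 (SE 0.25 over genes taken as independent). This lay above 0.30, the level the rule set beforehand derives from the contractile list's own median, but by less than its SE. That SE does not measure the spread between libraries. The median was that of Mfap5, at a mean of 1.68 CPM (adjusted p = 0.355). Fap and Thy1 (2.72 and 0.582 CPM) and Fbln2 did not pass either, so this test cannot decide. Pdgfra fell (−0.62). Pdgfrb and Cxcl12 were at means of 285 and 326 CPM over all libraries, so the line itself may express them. The 4 endothelial and pericyte markers tested also had a median of 0.62, 2 of them past the threshold, and a share of pericyte-like cells was not tested. Whether the proportion of such cells or expression within the epithelial cells changed, as a response to Id4 loss or to another target of the pool, stays open. The siRNA product line differs between the arms for these genes too and cannot be told apart from either.

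The real grouping gave 1331 changed genes and the highest of the other 9 splits of the 6 libraries 0 by edgeR (1683 at an unadjusted p under 0.05, against 3567). With 10 splits, of which 1 gave as many, no share under 0.05 is possible. The other 3 splits that part all 3 pairs gave 0, and with the block 0 against 5038 (at most 54 at an unadjusted p under 0.05, against 6145). Each of the other 9 splits holds libraries of both arms on each side, so the difference between arms widens the spread within sides. A count of 0 was therefore likely in advance, and these counts do not measure chance.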
